A study of Homo sapiens with 6 samples.

How the data were processed

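Small RNA libraries of 6 colorectal cancer cell lines, DLD_1, HCT116, lovo, RKO, sw480 and sw620, were sequenced, 1 library per line. Per the labels' protocols, RNA was taken with Trizol and libraries were built from 1 ug of total RNA with an Illumina TruSeq RNA kit. That kit is not one for small RNA, and the protocol text also mentions the omentum, which does not match cultured lines, so how these libraries were made is uncertain. The submitters' processing notes name Bowtie 0.12.2 and the mouse builds mm8 and mm9 without a role. The rows carry human miRNA names, so the build and miRNA annotation behind the counts are not given in the sources used here, and neither are the counting tool, its treatment of strand and multiply mapped reads, or any filter. The authors deposited 1 table with 1803 rows, 1654 with human miRNA names and 149 predicted miRNAs, and 2 columns per line. Per the file headers the first is a read count, and the values are whole numbers with different totals. The second is headed tpm. It was checked to be the deposited count divided by the column total and multiplied by 1000000, with a largest difference of 4.22e-05, so it is a CPM with no length term. The table held no columns of other samples and 0 repeated names.

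Lines were grouped by the cell line in the labels. Totals were 9352385 counts in DLD_1, 9118410 in HCT116, 8935164 in lovo, 8289364 in RKO, 6593151 in sw480 and 9077581 in sw620. A count of 3, taken as the one-sided 95% limit that 0 counts allow, corresponds to between 0.230 CPM in HCT116 and 0.639 CPM in DLD_1. TMM factors from edgeR 4.0.16 in R 4.3.3 gave normalised CPM, and log2 values were taken with a pseudocount of 1 CPM, which understates differences of low miRNAs. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

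With 1 library per line, no test across libraries was made. A miRNA was listed as different by a rule of size, 4-fold or more against the median of the other 5 lines, at 100 CPM or more in the line (higher) or in that median (lower). For sw620 against sw480 the same fold was used at 100 CPM or more in either library, with exact conditional binomial (Clopper-Pearson) 95% intervals of the count ratio. Single levels have exact Poisson intervals and shares Wilson intervals. Similarity was the Spearman correlation over miRNAs at 10 CPM or more in at least 2 lines, with intervals from 1000 bootstrap draws over miRNAs. Arm use was the 5p share over arm pairs with 200 or more counts in every line. For 19 lists of miRNAs, the median difference was placed among 10000 random lists of the same size, each member replaced by a miRNA from a window of 50 neighbours in mean expression. The lists were the miR-17-92 cluster and paralogs, the miR-200, let-7, miR-34, miR-29 and miR-30 families, the miR-192/194/215, miR-183/96/182, miR-99/100/125, miR-23/24/27 and miR-15/16 groups, colorectal tumour-raised, HOX-embedded, embryonic and placental, and chromosome 14 imprinted miRNAs, stromal, blood and other-tissue markers, and partners of the circular RNA recalled from memory. The design, lists, rule of size and alternatives were set before the data were examined. The named miRNAs were the 3 largest differences in each direction per line, the 10 largest in each direction for sw620 against sw480, the 5 arm pairs with the widest range, the 10 miRNAs with the highest median share, and list members.

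Hairpin positions, host genes and sequences came from GENCODE release 29 on GRCh38, matched by name for 1619 rows. GC content was that of 0.5 of the hairpin, the 5p or 3p side that holds the arm, known for 1294 rows, since mature sequences are not in the table. Facing arms of hairpins that overlap on opposite strands were compared where either had 100 counts or more. Those whose totals differed by 5% or less were treated as possible duplicates, which left 17 rows out of 1 alternative, out of the arm comparison and out of the GC trend. These 17 rows held between 2.66% of counts in lovo and 8.18% in sw620. Rows without an arm suffix were not searched, so the share may be understated. For example, miR-103b stayed in, with 9975 CPM in DLD_1 against 10416 CPM for miR-103a-3p. Likewise miR-548bc and miR-548f-5p, each with 950 counts in sw620 and 12 in sw480, were both kept.

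Alternatives were total-count CPM, DESeq2 1.42.0 size factors, pseudocounts of 0.1 and 10 CPM, minimum levels of 10 CPM or none, 2-fold and 8-fold rules, the 3 most abundant miRNAs of each library left out, other references, other similarity measures and list filters, arm pairs with 50 counts, and 1 count as detected. A further 3 were chosen after the data were seen: possible duplicates left out, the linear trend with GC content removed, and a reference without DLD_1 and sw620. The rule of size was tested on simulated data drawn from sw480 at the depths of sw620 and sw480, with 200 of 1803 miRNAs changed. Of miRNAs at 100 CPM or more in either simulated library, all 50 raised 8-fold, 50 raised 16-fold, 27 lowered 8-fold and 22 lowered 16-fold were listed, and 0 of 52 unchanged ones. The intervals of the count ratio held the true value, moved by the median shift of the unchanged miRNAs, in 95.0% of cases. Apart from depth and the planted changes, the simulated libraries differed by counting error only. These results therefore say nothing of false listings from preparation, base composition or scaling between real libraries. The placing of lists was tested on simulated data in 2 ways. In the first, 20 lists of 8 were drawn among the raised miRNAs while 200 miRNAs differed, and 45% of them lay in the upper 2.5% of random lists, since the random lists held changed miRNAs too, and 0 of 100 unchanged lists lay in either tail. A simulation added after that result, with only the 8 members of each of 100 lists raised 2-fold, put 100% in the upper tail and 4% of unchanged lists in either tail. Where many miRNAs differ, as between these lines, a list can therefore differ without a high or low percentile.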

Results

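Mature miRNA levels were measured by sequencing in 6 established human colorectal cancer cell lines, named DLD_1, HCT116, lovo, RKO, sw480 and sw620, with 1 library per line. The series concerns a circular RNA, hsa_circ_0084927, in colon adenocarcinoma and the RNAs that compete with it for miRNAs. Its description also mentions patients, whose samples are not analysed here. With 1 library per line no difference has a replicate check, so no p-value is given across libraries, and each difference is one between these libraries. Intervals are 95% intervals that cover counting error only, since copies made by PCR are not independent molecules. The libraries held between 6593151 counts in sw480 and 9352385 counts in DLD_1. The totals were 9118410 in HCT116, 8935164 in lovo, 8289364 in RKO and 9077581 in sw620. Between 506 miRNAs in sw620 and 716 in HCT116 reached 10 counts. Levels below are TMM-normalised CPM (counts divided by the effective library size, times 1000000). A difference for a line is log2(CPM + 1) in that line minus the median of the other 5 lines, and a miRNA is listed as higher or lower when it differed by 4-fold or more and reached 100 CPM in the line (higher) or in the median of the others (lower). TMM factors ranged from 0.502 in DLD_1 to 1.77 in sw480. Scaling by total counts instead moved the median difference by between -0.99 in DLD_1 and 0.82 in sw480, and DESeq2 size factors moved it by up to 0.40 in sw620, so smaller differences depend on the scaling.

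A few miRNAs held most of the counts in each line, and the leading one differed. The miRNA miR-10a-5p, which lies in the HOXB gene cluster, led in DLD_1 (37.6%, Wilson interval 37.6 to 37.7), RKO (39.7%, 39.6 to 39.7) and sw480 (11.4%, 11.3 to 11.4). In HCT116 and lovo miR-100-5p led, with 19.3% (19.3 to 19.3) and 23.1% (23.1 to 23.2). In sw620 the leading miRNA was miR-21-5p, widely described as raised in tumours, with 26.5% (26.4 to 26.5). By median share over the 6 lines, miR-21-5p came first (8.51%, range 4.71 to 26.5), then miR-10a-5p (7.88%, 4.02 to 39.7), let-7i-5p (4.23%, 1.07 to 8.37), miR-151a-3p (3.55%, 0.745 to 8.19), let-7g-5p (2.71%, 0.688 to 3.11) and miR-30d-5p (2.70%, 0.893 to 3.63). They were followed by miR-148a-3p (2.51%, from 0.873 in sw480 to 23.7 in sw620), let-7a-5p (2.49%, 0.449 to 2.96), miR-7-5p (2.40%, 0.242 in lovo to 8.02 in sw620) and miR-3529-3p (2.37%, 0.241 to 7.90). The widest Wilson interval of these shares was 0.0666 percentage points. The 10 leading miRNAs of each library together held from 53.7% of counts in sw480 (53.6 to 53.7) to 84.8% in DLD_1 (84.8 to 84.8). The hairpins of miR-7-2 and miR-3529 overlap on opposite strands of chromosome 15, and their facing arms had near-equal counts in total, 1798289 and 1777293, so the values of these miRNAs are uncertain. The same holds for the other facing pairs named below, which are marked where they appear.

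HCT116 and lovo had closely matching miRNA profiles, and sw620 stood apart from most of the others. Across 379 miRNAs at 10 CPM or more in at least 2 lines, HCT116 and lovo had a Spearman correlation of 0.958 (bootstrap interval over miRNAs 0.942 to 0.969), and the next closest pair, HCT116 and sw480, had 0.824 (0.771 to 0.868). Only 8 miRNAs differed by 4-fold or more between HCT116 and lovo at 100 CPM or more in either. They were picked out after their values were seen. Those higher in HCT116 were miR-7974 (1450 against 69.5 CPM), miR-7-5p with its facing miR-3529-3p (22231 against 1879 CPM for miR-7-5p) and miR-4521, and those lower were both arms of miR-30a (225 against 1371 CPM for the 5p arm), miR-1260b and miR-139-5p. DLD_1 and sw620 were number 4 of the 15 pairs, with 0.806 (0.757 to 0.850). The lines sw480 and sw620, known to have been derived from a primary tumour and a lymph node metastasis of the same patient, had 0.646 (0.573 to 0.712), which placed them 12 of 15. The lowest value was 0.567 (0.489 to 0.641), for lovo and sw620. These correlations run across miRNAs, which are not independent replicates. The differences also followed base composition. Over 322 miRNAs with a GC value for the arm of the hairpin stem they come from, the Spearman correlation of GC content with the difference sw480 minus sw620 was 0.489, and with lovo minus sw620 it was 0.511, whereas with HCT116 minus lovo it was -0.227.

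**Figure D1:**
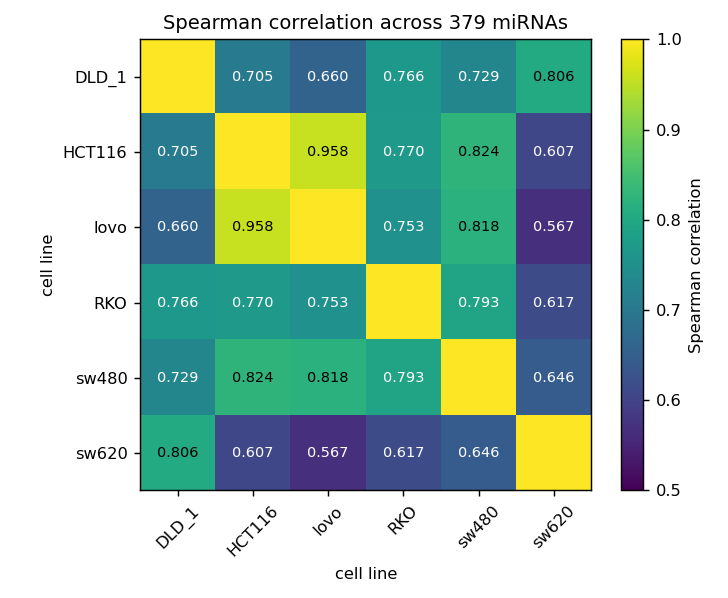
Heat map of the Spearman correlation across 379 miRNAs for each pair of the 6 lines, with cell lines on both axes and 1 library per line. The pair HCT116 and lovo, at 0.958, is the highest, and lovo and sw620, at 0.567, the lowest.

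DLD_1 held high levels of miR-582-3p, miR-372-3p and miR-1-3p. The miRNA miR-582-3p, from an intron of PDE4D (GRCh38 chromosome 5, 59703606 to 59703703), reached 1376 CPM (1342 to 1409.5) against a median of 0.691 CPM in the others, although sw620 had more. The embryonic stem cell miRNA miR-372-3p stood at 678 CPM (655 to 702) against 1.07 CPM, and miR-1-3p, a muscle miRNA, at 1218.5 CPM (1187 to 1250.5) against 2.92 CPM. The largest differences in the other direction were those of both arms of miR-455, from an intron of COL27A1 (chromosome 9, 114209434 to 114209529). The 3p arm had 1.49 CPM (0.600 to 3.07) against 111 CPM and the 5p arm 7.46 CPM (5.19 to 10.4) against 287 CPM. They were followed by miR-125a-5p, with 88.2 CPM (79.9 to 97.1) against 2174 CPM. In all, 36 miRNAs were higher and 15 lower in DLD_1. The median GC content of the hairpin arm was 40% in the higher and 53.5% in the lower ones. By total-count CPM the split was 16 higher and 49 lower.

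HCT116 and lovo had in common high levels of the miR-100 and miR-125b-1 hairpins, which lie in introns of the MIR100HG transcript (chromosome 11, 122152229 to 122152308 and 122099757 to 122099844). In HCT116 the largest higher differences were those of miR-125b-1-3p (744 CPM, 729 to 759, against 7.73 CPM), miR-125b-5p (4768 CPM, 4731 to 4806, against 69.9 CPM) and miR-342-3p (169.6 CPM, 163 to 177, against 3.41 CPM). In lovo they were those of miR-125b-5p (9007.5 CPM, 8953 to 9062.5), miR-125b-1-3p (804 CPM, 788 to 821) and miR-100-5p (179319 CPM, 179075 to 179564, against 5792 CPM). In both lines the lower miRNAs were led by miR-582-3p, miR-215-5p and miR-192-5p. Levels of miR-192-5p were 124 CPM (118 to 129.8) in HCT116 and 108 CPM (102 to 114) in lovo against 5235 CPM. HCT116 had 9 counts of miR-582-3p and 9 of miR-215-5p, and lovo had 4 and 26. The difference of miR-582-3p was -7.56 in HCT116 and -7.89 in lovo, but 0.33 and -0.33 with DLD_1 and sw620 left out of the reference, because the miRNA was high in only DLD_1, sw480 and sw620. HCT116 had 9 higher and 7 lower miRNAs, and lovo 14 and 12. Each line was in the reference of the other. Without lovo in the reference HCT116 had 13 higher and 24 lower miRNAs, 37 in all, without sw480 it had 12 and 20, and without RKO 11 and 13. For lovo the counts were 20 and 36 without HCT116, 19 and 29 without sw480 and 17 and 25 without RKO, so in both lines the lower miRNAs were then more numerous. By total-count CPM HCT116 had 21 higher and 7 lower, and lovo 25 and 9.

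RKO was marked by miRNAs of the miR-371 to miR-373 cluster on chromosome 19, normally active in embryonic stem cells, and by near absence of miR-31-5p. The miRNA miR-372-3p (chromosome 19, 53787890 to 53787956) reached 1028 CPM (1003 to 1053) against a median of 1.07 CPM in the others. DLD_1 was the next highest line, with 678 CPM of miR-372-3p and 77.1 CPM of miR-371a-5p. In RKO miR-372-3p was followed by miR-371a-5p (233.9 CPM, 222 to 246, against 0.0867 CPM) and the facing miR-371b-3p (233 CPM), which lie on opposite strands and had 1827 and 1818 counts in total, so their levels are uncertain. Lower in RKO were miR-31-5p (2.73 CPM, 1.59 to 4.37, against 1301 CPM), whose hairpin lies in an intron of MIR31HG on chromosome 9, and miR-100-5p (71.1 CPM, 64.6 to 78.0, against 17257 CPM). The library held 0 counts of miR-582-3p (interval 0 to 0.592 CPM) against a median of 319 CPM. That difference, -8.32, was -0.76 with DLD_1 and sw620 left out of the reference. RKO had 30 higher and 12 lower miRNAs, and 22 and 21 by total-count CPM.

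The miRNA miR-155-5p, which acts in immune cells and is often raised in tumours, separated sw480 from the other 5 lines. It came to 523 CPM (509 to 536) against a median of 1.21 CPM, and the next highest line was DLD_1 with 49.4 CPM. Its hairpin lies in an exon of MIR155HG (chromosome 21, 25573980 to 25574044). The next largest were miR-582-3p (319 CPM, 309 to 329, against 0.691 CPM) and miR-486-3p (703 CPM, 688 to 719, against 34.4 CPM). The hairpins of miR-486 overlap on opposite strands, and its arms had near-equal counts in total, 10761 and 10973, so their levels are uncertain. The largest lower differences were those of miR-4326 (1.54 CPM, 0.915 to 2.44, against 162 CPM), miR-100-5p (519.6 CPM, 507 to 533, against 17257 CPM) and miR-95-3p (14.7 CPM, 12.6 to 17.0, against 303 CPM). The counts were 20 higher and 14 lower, and 49 and 7 by total-count CPM.

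The sw620 library departed from the others at more miRNAs than any other line, 56 higher and 39 lower. The higher ones were led by miR-582-3p (3171 CPM, 3130.2 to 3212, against 0.691 CPM), miR-1-3p (4005 CPM, 3959.7 to 4051, against 2.92 CPM) and miR-374a-3p (2079 CPM, 2046 to 2112, against 2.69 CPM). In each of these DLD_1 was the next highest line. The lower ones were led by miR-744-5p (1.76 CPM, 0.938 to 3.01, against 882 CPM), from an intron of the kinase gene MAP2K4 (chromosome 17, 12081899 to 12081996), miR-1307-3p (134 CPM, 126 to 143, against 5091 CPM) and miR-574-5p (12.9 CPM, 10.4 to 15.7, against 315 CPM). The median GC content was 43.2% in the higher and 56.9% in the lower miRNAs. Total-count CPM gave 49 higher and 54 lower, and DESeq2 size factors 72 and 28.

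**Figure D2:**
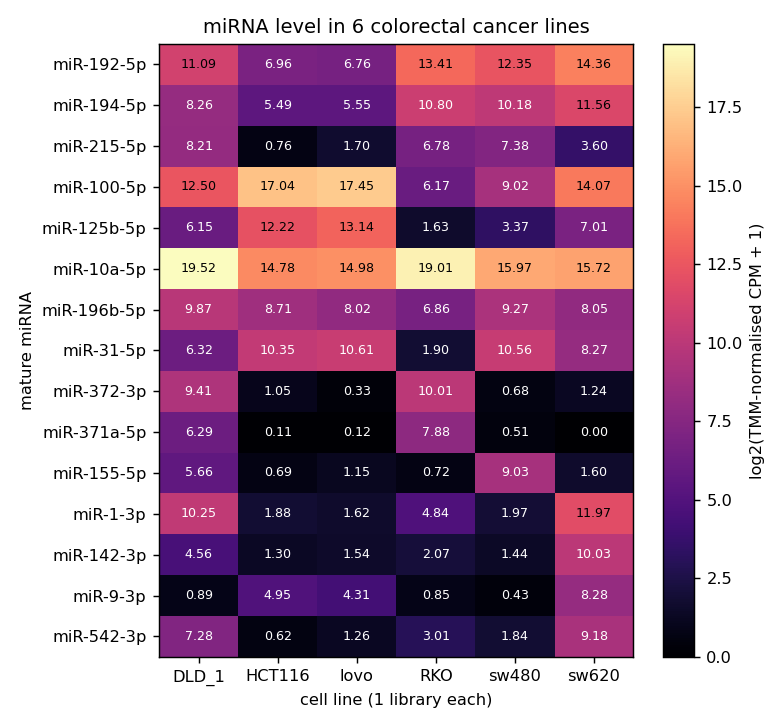
Heat map of log2(TMM-normalised CPM + 1) of 15 members of the miRNA lists, chosen after their values were seen, in the 6 lines with 1 library each. The miRNA miR-192-5p is at 6.96 in HCT116 and 6.76 in lovo and at 11.09 to 14.36 in the other lines, and miR-372-3p is at 9.41 in DLD_1 and 10.01 in RKO and at most 1.24 elsewhere.

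The lists of related miRNAs set the lines apart in several ways. Each median below is the median difference over the list's members with counts, and its percentile is its place among 10000 random lists matched on mean expression, which describes these libraries and is no test. Counts of members 4-fold apart are over those that reached 10 CPM in a line. The intestinal miR-192, miR-194 and miR-215 group, made by 2 hairpin clusters active in gut epithelium and responsive to p53 (chromosome 11, 64891137 to 64891439, and chromosome 1, 220117853 to 220118241), was low in HCT116 (median -4.25, percentile 0.0) and lovo (-4.15, percentile 0.0). All 5 members that reached 10 CPM were 4-fold lower in each. Its median was high in RKO (2.43, percentile 99.9), sw480 (2.05, 99.99) and sw620 (2.14, 99.6), and lower in DLD_1 (-1.25, 0.94). Against this, miR-215-5p was highest in DLD_1, at 295 CPM, and 4-fold lower in sw620 (difference -3.18), at 11.1 CPM. The miR-99, miR-100 and miR-125 group was low in RKO (-2.95, 0.0) and DLD_1 (-1.57, 0.040), and in HCT116 and lovo 3 of its 6 expressed members were 4-fold higher. Its members on chromosome 19, miR-99b-5p and miR-125a-5p, were higher in RKO (differences 1.52 and 2.39), against the median of the group, and were the 2 members 4-fold lower in DLD_1 (-4.32 and -4.61). The level of miR-99b-5p was 24509 CPM in RKO, 634 CPM in DLD_1 and 726 CPM in sw620. Embryonic and placental miRNAs were high in RKO (median 1.29, percentile 100) and DLD_1 (0.28, 97.3), where 5 and 4 of the 5 expressed members were 4-fold higher. Of the miR-302 and placental cluster members only miR-516b-5p passed 10 CPM, with 14.9 CPM in RKO.

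Several families had high members in both sw620 and DLD_1. The group of miR-15, miR-16 and the cell cycle repressors of the miR-424 to miR-450 hairpins on chromosome X had a median of 2.32 in sw620 (percentile 99.97) and 1.49 in DLD_1 (99.3), against -1.43 in HCT116 (0.0), -1.09 in lovo (0.41) and -1.09 in sw480 (0.61), with 1.07 in RKO (97.8). Its median GC content was 41.8%. Among the 15 expressed members of the MYC-activated miR-17-92 cluster and its paralogs, 6 were 4-fold higher in sw620 and 6 in DLD_1. The miRNA miR-19b-3p stood at 1757 CPM in sw620 and 470.5 CPM in DLD_1 against 2.43 to 16.8 CPM in the other lines, while miR-92a-3p stood between 6814 and 14143 CPM in all 6. Each of these miRNAs has 2 hairpins, on chromosomes 13 and X, which the counts do not tell apart. The list median was 0.47 in sw620 (98.6) and -0.86 in lovo (0.11). In the miR-29 family, whose median GC content was 40%, miR-29b-3p reached 900 CPM in sw620 and 467 CPM in DLD_1 against 10.1 to 27.6 CPM elsewhere. The family's median in sw620 was 0.71 (81.0), but -0.18 by total-count CPM, and miR-29a-3p lay between 2565 and 5973 CPM in the 6 lines. With the GC trend removed, the median over expressed members fell in each of these lists. In the miR-29 family it was -0.74 in sw620 in place of 0.71 and -0.24 in DLD_1 in place of 1.07. In the miR-15, miR-16 and chromosome X group it was 1.59 in sw620 in place of 2.92 and 0.38 in DLD_1 in place of 1.90. In the miR-17-92 list it was 0.62 in sw620 in place of 1.41 and 0.36 in DLD_1 in place of 0.77. The miR-30 family had its lowest medians in sw480 (-0.60, percentile 5.93) and sw620 (-0.48, 47.3). Both changed sign under total-count CPM (0.32 and 0.19), and that of sw620 also with DESeq2 size factors (0.09).

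Epithelial and differentiation-linked families had smaller list medians than the intestinal group. In the miR-200 family, which maintains epithelial identity by repressing ZEB1 and ZEB2, the median ran from -0.91 in HCT116 (percentile 0.49) to 1.09 in DLD_1 (96.8). In sw620 it was -0.57 (42.8), and 0.56 over the 8 members with a GC value when the GC trend was removed. Its members went in both directions: miR-200c-3p stood at 1549 CPM against 14499 to 30927 CPM in the other lines, and miR-141-5p at 294 CPM, as in DLD_1 (296 CPM), against 16.2 CPM in sw480. The let-7 family, repressors of RAS and HMGA2, had its lowest median in sw620 (-1.61, percentile 6.99), where let-7c-5p, let-7d-5p and let-7e-5p were 4-fold lower, and its highest in RKO (1.10, 97.6). Among the miR-183, miR-96 and miR-182 cluster, sw480 had 4-fold lower miR-96-5p (190.0 CPM) and miR-182-5p (2117 CPM), with a list median of -0.62 (8.57). The HOX-embedded miRNAs had medians of 1.16 in RKO (98.3) and 0.99 in sw480 (98.9), and miR-615-3p, from an intron of HOXC4, ran from 38.8 CPM in DLD_1 to 4907 CPM in sw480. The 7 members of the miR-23, miR-24 and miR-27 list stayed within 4-fold of the median of the other 5 lines in each line, with list medians between -0.38 in HCT116, which was 0.18 by total-count CPM, and 0.58 in lovo. In the p53-induced miR-34 family only miR-34a-5p passed 10 CPM, between 71.8 CPM in sw480 and 536 CPM in RKO, so its median in sw480 (-0.57, percentile 0.18) rests mostly on members near the floor. Among miRNAs often raised in colorectal tumours the medians ran from -0.24 in sw480, which was 1.10 by total-count CPM, to 0.45 in sw620, while single members ranged widely. For example, miR-135b-5p stood at 947 CPM in sw620 and 21.9 CPM in DLD_1.

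Some markers of other cell types were present at measurable levels in some lines, above all sw620. The blood and immune list had a median of 1.84 in sw620 (percentile 99.2), with miR-146a-5p at 1246 CPM, miR-142-3p at 1042 CPM and miR-142-5p at 205 CPM. The leukocyte miRNAs miR-223-3p and miR-150-5p stood at 4.88 and 7.59 CPM there, within the range of the other lines. Of the 5 expressed members 4 were 4-fold higher in sw620. The exception was miR-486-5p, uncertain because of its facing arm, with 35.5 CPM in sw620 and 718 CPM in sw480. The stromal and smooth muscle list had a median of 1.25 in sw620 (99.0), led by miR-1-3p, and -0.78 in sw480 (0.60). In it, miR-145-5p stood at 237 CPM in HCT116 and 140.4 CPM in lovo and at 9.35 CPM or less elsewhere. Of this list, miR-1-3p, miR-143-3p and miR-145-5p alone reached 100 CPM in any line. The muscle miRNAs miR-133a-3p and miR-133b, miR-214-3p and the miR-199 members did not. Among liver, brain and endothelial markers miR-9-5p, a neural miRNA, reached 6146 CPM in sw620 and 2118 CPM in HCT116 against 97.5 CPM in sw480. The list medians were 0.83 in HCT116 (98.6), 1.11 in lovo (98.3) and -1.14 in DLD_1 (1.13). In sw620 the median was 0.84, at percentile 84.55. The imprinted cluster on chromosome 14 had few expressed members, 4 of 26, and its median differences lay between -0.22 in DLD_1 and 0.39 in HCT116. Of the 4 miRNAs recalled from other work as partners of the circular RNA, 2 had rows. Of these, miR-142-3p was highest in sw620 and miR-1179 had no more than 0.0767 CPM in any line.

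The comparison of sw620 with sw480 sets a lymph node metastasis line against the primary tumour line of the same patient. The muscle miRNA miR-1-3p was 1373-fold higher in sw620 (983 to 1984), with 4005 against 2.92 CPM, and miR-374a-3p, from an intron of FTX on the X chromosome, was 1102-fold higher (727 to 1758). From the miR-17-92 list, miR-19b-3p was 621-fold (442 to 902) and miR-19a-3p 1082-fold higher (369.6 to 5249.5, from 2053 against 3 counts). The blood cell miRNA miR-142-3p was 607-fold higher (393 to 995) and the neural miR-9-3p 902-fold (352 to 3312). The heart miRNA miR-499a-5p, from an intron of MYH7B, was 1012-fold higher (433 to 3119). The facing miR-499b-3p had 2779 against 4 counts, and these antisense arms are uncertain. The miRNAs miR-590-3p (1125-fold, 311 to 9295, from 1423 against 2 counts) and miR-542-3p (225-fold, 157 to 334) completed the 10 largest by log2(CPM + 1). The count ratio alone was larger than that of miR-542-3p for miR-205-5p (653-fold, 223 to 3170) and miR-548f-3p (420-fold, 143 to 2041), each from 3 counts in sw480. In the other direction miR-744-5p was 500.5-fold lower (293 to 940.3), miR-155-5p 257-fold lower (156 to 459) with 2.03 against 523 CPM, and miR-615-3p 99.2-fold lower (89.5 to 110.2). They were followed by miR-185-3p (111-fold, 69.96 to 187), miR-1303 (70.1-fold, 54.2 to 92.4), miR-193a-5p (118-fold, 57.0 to 293), miR-1260b (63.5-fold, 46.8 to 88.7), miR-1307-3p (37.9-fold, 35.6 to 40.4), miR-99b-3p (37.0-fold, 33.6 to 40.7) and miR-1287-5p (41.9-fold, 30.2 to 60.0).

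Of 212 miRNAs at 100 CPM or more in either library, 64 were higher and 51 lower in sw620, together 54.2%, and the counting interval of each excluded no difference. That follows from the rule of size at this depth and is no added support. The higher miRNAs had a median GC content of 44.3% and the lower ones 57.8%. Among the lists, the recalled partners of the circular RNA had the highest place, with a median of 4.29 (percentile 100), which rests on miR-142-3p, the 1 member that reached 10 CPM. The miR-15, miR-16 and chromosome X group came next, with a median of 2.58 (99.9) and 5 of 8 expressed members 4-fold higher. The stromal list had 2.16 (99.9) and the blood list 1.94 (98.5). Of the 5 expressed members of the blood list 4 were 4-fold higher and 1 was 4-fold lower. The lower one was miR-486-5p, with 35.5 against 718 CPM, whose level is uncertain because of its facing arm. The chromosome 14 list stood at percentile 99.6 with a median of 0.01, and that was -0.10 by total-count CPM. With the GC trend removed, the median over the 15 expressed members of the miR-17-92 list was -0.16 in place of 0.88. That of the 8 expressed members of the miR-15, miR-16 and chromosome X group was 2.13 in place of 3.45. That of the let-7 family was -2.19 in place of -1.39. The intestinal group had no settled direction: its median was -0.36 (60.7), 0.03 with DESeq2 size factors and 1.06 (94.6) over the 5 members that reached 10 CPM, and miR-192-5p was higher (21003 against 5235 CPM) and miR-215-5p lower (11.1 against 166 CPM). Total-count CPM gave 42 higher and 98 lower, and DESeq2 size factors 76 and 37, with a shift of the median difference of -1.12 and 0.41.

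**Figure D3:**
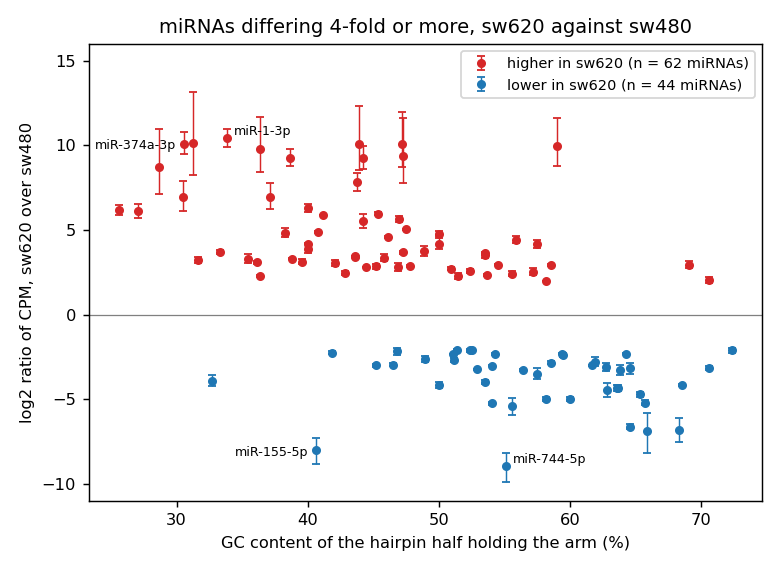
The log2 ratio of CPM, sw620 over sw480, against the GC content in percent of the part of the hairpin that holds the arm, for the 106 of the miRNAs differing 4-fold or more that have a GC value; bars are 95% counting intervals. The 62 miRNAs higher in sw620 lie mostly at lower GC content than the 44 lower ones.

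The share of counts from the 5p arm of a hairpin does not depend on scaling between libraries, and it differed between lines for a minority of hairpins. Of 98 pairs of arms with 200 or more counts in every line, 24 had shares that ranged over more than 20 percentage points, while the median range was 2.21 points. The widest range was that of miR-374a, whose 5p share was 32.7% in sw620 (32.1 to 33.3) and 41.7% in DLD_1 (40.2 to 43.2) and at least 93.6% in the other 4 lines. For miR-106b it was 66.8% in sw620 (66.0 to 67.6) and 29.9% in DLD_1 (28.8 to 30.9) and at most 6.21% elsewhere. The 5p share of miR-141 was 83.8% in sw620 (82.3 to 85.1) and 78.0% in DLD_1 (76.0 to 79.8), and between 21.3 and 35.8% elsewhere. For miR-340 the shares were 97.9% (97.5 to 98.2) and 94.8% (94.0 to 95.5), against 41.7 to 60.3% elsewhere. For miR-365a it was 93.4% in sw620 (92.3 to 94.4), 63.9% in DLD_1 (60.0 to 67.6) and 29.3% in sw480 (26.5 to 32.4). In 15 of these 24 pairs DLD_1 and sw620 both lay outside the other 4 lines on the same side. Among the other pairs of lines, lovo and sw480 did so most often, in 10 of the 24. Over all 98 pairs of arms, DLD_1 and sw620 did so in 43.9% and lovo and sw480 in 23.5%, and a pair of lines chosen at random would do so in 13.3%.

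**Figure D4:**
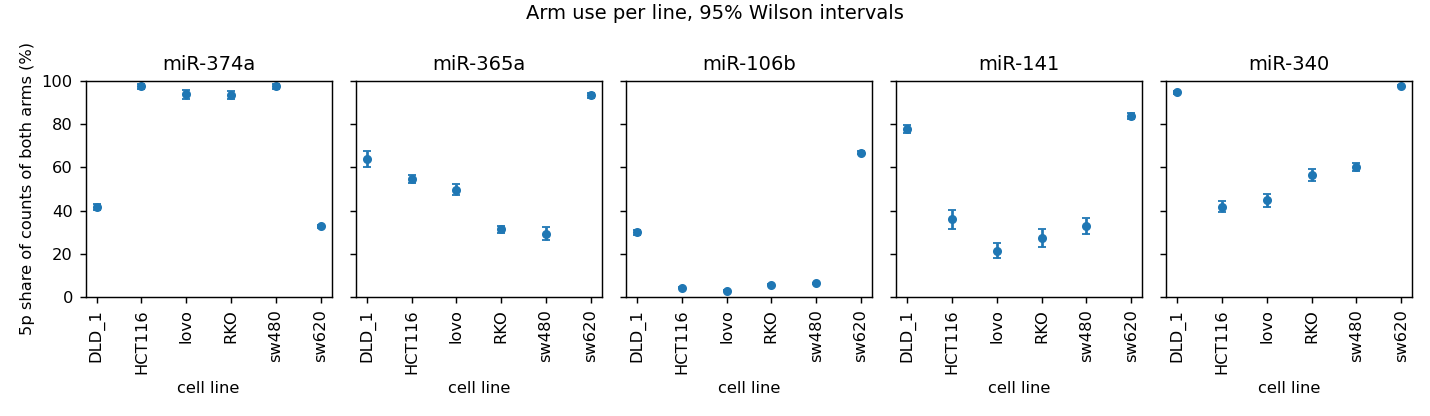
The 5p share in percent of the counts of both arms for the 5 hairpins with the widest range, by cell line, as points with 95% Wilson intervals. DLD_1 and sw620 stand together and apart from the other lines for miR-374a, miR-141 and miR-340.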

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

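The 149 predicted miRNAs without a human miRNA name are in none of the 19 lists. Their rows were kept in the totals, the scaling, the numbers of miRNAs detected and the pool of random lists. The correlation with no minimum, over 1803 rows, held them too. Their counts were picked out because they lay above the 3 counts that a count of 0 allows. They came to 299 counts in DLD_1, 627 in HCT116, 777 in lovo, 330 in RKO, 724 in sw480 and 165 in sw620, between 0.00182% of all counts in sw620 and 0.0110% in sw480. The most abundant were novel_166 with 295 counts over the 6 lines, novel_181 with 206 and novel_739 with 205. Their sequences are not in the table, so no position can be given, and no explanation was tested.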

How the results depend on the processing

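Among the alternatives, DESeq2 size factors and both pseudocounts left each total of listed miRNAs within 1.5 times its value, as did the mean of the other 5 lines as reference. The same held for 3 alternatives chosen after the data were seen: possible antisense duplicates left out, the GC trend removed, and DLD_1 and sw620 left out of the reference. Totals by line were 51 in DLD_1, 16 in HCT116, 26 in lovo, 42 in RKO, 34 in sw480 and 95 in sw620. Similar totals did not mean the same miRNAs. With the GC trend removed, where miRNAs without a GC value drop out, 35 of the 51 in DLD_1 and 64 of the 95 in sw620 stayed listed. In RKO 39 of the 42 did. With DESeq2 size factors 43 stayed listed in DLD_1, 84 in sw620 and 40 in RKO. Total-count CPM gave 28 in HCT116 and 56 in sw480, and for sw620 against sw480 it gave 42 higher and 98 lower. A minimum of 10 CPM gave 102 in DLD_1, 44 in HCT116, 75 in lovo, 79 in RKO, 76 in sw480 and 172 in sw620, with 107 higher and 105 lower in sw620 against sw480. No minimum gave 122, 65, 93, 94, 98 and 223, with 129 and 136. The 2-fold rule gave 95, 54, 75, 84, 81 and 149. The 8-fold rule gave 31 in DLD_1, 16 in lovo, 17 in sw480 and 60 in sw620, with 28 lower in sw620 against sw480. These counts follow from the looser or stricter rule. Leaving out the 3 most abundant miRNAs of each library gave 25 in HCT116 and 40 in lovo, and the cause was not tested. It also cut the effective library size, in HCT116 from 13029978 to 5047908 and in lovo from 11532712 to 4558926, so 100 CPM stood for fewer counts. Leaving each other line out of the reference gave 16 to 37 in HCT116, highest without lovo, and 23 to 56 in lovo, highest without HCT116, and the cause was not tested. Values without sw480 were 32 and 48, and without RKO 24 and 42. In sw480 the split was 22 higher and 28 lower without HCT116, and likewise without lovo. DLD_1 had 23 higher and 21 lower with the GC trend removed, and 33 and 26 without the 3 most abundant miRNAs, which gave 36 and 14 in sw480.

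The median of the chromosome 14 list in sw620 against sw480 was -0.10 by total-count CPM against 0.01, near the floor. The difference of miR-582-3p was 0.33 in HCT116, -0.33 in lovo and -0.76 in RKO with DLD_1 and sw620 left out of the reference, since the remaining lines mostly lack it. The correlation of sw480 and sw620 was 0.533 with a minimum of 100 CPM, and that of HCT116 and lovo 0.856 with no minimum and 0.971 by Pearson correlation. HCT116 and lovo were the closest pair under each of these 5 alternatives, and sw480 and sw620 stayed 12 of 15, or 11 with the GC trend removed. With 1 count as detected, 1079 miRNAs were seen in DLD_1, 1318 in HCT116, 1289 in lovo, 1112 in RKO, 1182 in sw480 and 861 in sw620. No names repeat in the table, so summing rows of a miRNA was not run. The depth limits miRNAs near 1 CPM most, where a few counts set the ratio, and the scaling limits 4-fold calls too: total-count CPM kept 93 of the 115 miRNAs for sw620 against sw480 and 31 of the 51 in DLD_1.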

Other observations

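Hairpin clusters that lie within 10 kb on the same strand were summarised after the data were seen, for those with 3 or more expressed miRNAs. The cluster from MIR532 to MIR502 (chromosome X, 50003148 to 50014683) was high in RKO, with a median difference of 2.95 over 12 miRNAs and a median level of 266 CPM, against 19.5 CPM in sw480 and 22.4 CPM in lovo. The cluster of miR-181c and miR-181d (chromosome 19, 13874699 to 13875011) was high in sw620, with a median of 3.32 over 3 miRNAs and a median level of 54.4 CPM against 3.05 to 8.84 CPM elsewhere. The cluster from MIR99B to MIR125A, which also holds let-7e (chromosome 19, 51692612 to 51693339), was low in DLD_1 (median -4.17) and sw620 (-3.97) over 6 miRNAs, and all 6 were lower in sw620 than in sw480. The cluster of miR-143 and miR-145 (chromosome 5, 149428918 to 149430733) had medians of 4.55 in HCT116 and 4.26 in lovo over 3 miRNAs. These were miR-143-3p and both arms of miR-145, so the medians rest on miR-145. The level of miR-143-3p was 136 CPM in HCT116 and 121 CPM in lovo. It was higher in DLD_1 (197 CPM) and sw620 (452 CPM), and lower in RKO (50.9 CPM) and sw480 (68.2 CPM).

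In the paragraphs that follow, the correlation within hairpins and the count of hairpins with both arms apart were fixed before their results were seen, and the other 7 tests were chosen only afterwards. Of the 115 miRNAs that differed 4-fold between sw620 and sw480, 106 had a GC value, and 83 of them stayed 4-fold apart in the same direction with the linear GC trend removed. So this linear trend, with the GC content of the hairpin side, does not by itself account for most of these differences. The GC content of the mature miRNAs was not known, so a trend with it, or one that is not linear, stays open. With the 3 most abundant miRNAs of each library left out, 103 of the 115 stayed listed, and the total was then 141. Some of the 115, such as miR-21-5p, were themselves among those left out. TMM scaling already sets aside extreme and abundant miRNAs, so most of the 115 were likely to stay. Neither value therefore decides whether a few abundant miRNAs taking most counts were the cause. By total-count CPM, 93 of the 115 stayed listed, with 42 higher and 98 lower in all. The effective library size of sw620 fell from 7376148 to 2566514 and that of sw480 from 11658929 to 4555013, so 100 CPM stood for fewer counts. Whether the libraries differed in a preference for base composition stays open. Across 90 hairpins, the difference of the 5p arm minus that of the 3p arm had a Spearman correlation of -0.204 with the GC difference of the arms (two-sided permutation p = 0.0549), too weak to decide. A difference between the lines themselves could also be the source, and is untested because each line has 1 library.

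The closeness of HCT116 and lovo is not that of 1 library deposited under both names, since their counts differed by a chi-square of 858 per degree of freedom, against 3251 in the next closest pair. A shared linear trend with the GC content of the hairpin side does not account for the closeness. With that trend removed, the correlation of the pair stayed 0.155 above the next highest, 0.967 against 0.812. Other shared effects of base composition, such as one that is not linear, stay open. In 2 of 71 hairpins, miR-30a and miR-139, both arms were 4-fold apart in the same direction, which meets the bound of 2 set beforehand as arguing against the same cells with differences from preparation only, though thinly, since a bound of 5, considered after the value was seen and not kept, would have left it open. Mixing of the libraries with each other stays open: with the largest parts that single miRNAs allow taken out (5.15% of the HCT116 level from lovo and 12.0% of the lovo level from HCT116), the correlation was 0.921, and its gap of 0.0965 to the next highest lay below the 0.1 set for arguing against it. A mislabelled library, material of another source in both libraries, or a biological likeness of the lines may be the source, and these were not tested.

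Arms that face each other on opposite strands had near-equal counts, and 17 of 26 such pairs with 100 counts or more had totals within 5%. The log2 ratio of facing arms ranged over the lines by a median of 0.0597, against 3.12 for neighbours within clusters. That does not decide whether both strands are transcribed and processed alike, since a steady ratio would follow from that too. Counts of miR-3065-5p and miR-338-3p were the same in each of the 6 lines, 593 in total for each. Those of miR-550a-3p and miR-550b-2-5p were also the same, 351 in total. Separate molecules would be expected to differ by counting error. Other pairs did differ, down to 631 counts of miR-374b-3p against 17 of miR-374c-5p. A candidate explanation is that the same reads were counted under both names, as a count without strand would give. The largest such pair was miR-7-5p and miR-3529-3p.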
